A study of Drosophila melanogaster with 3 samples.

How the data were processed

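The series holds ChIP-seq of Eip75B tagged with eGFP in whole Drosophila melanogaster prepupae, precipitated with an antibody against GFP. Per the labels, chromatin was sheared by sonication to a size range of 200 to 800 bp, males and females were pooled, and 3 biological replicates form 1 group. Replicate numbers were taken from the labels. Replicates were compared with each other and treated as separate biological samples because the labels call them so.

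The authors deposited peak lists. Per the labels, there is a list for each replicate and a list for the 3 replicates pooled, each made to be ranked for IDR (the irreproducible discovery rate, which compares the ranks of peaks between replicates) and therefore holding background as well as peaks. A shorter list of optimal peaks after IDR was deposited for the group. Each list was deposited on the dm6 build and on the older dm3 build. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The number of reads per library is not given either, so the depth and the precision it gives are unknown. The signal in each list is the peak caller's own value per region as the authors deposited it. It was higher in the pooled list than in the replicates (highest value 3259 against 1115, 966 and 1112), and was used only to rank and describe peaks within 1 list. The −log10 q-value that the authors deposited with each region had the same highest value in 91.2% of the optimal peaks and was therefore not used for ranking. The optimal list on dm6 was found to be the 7803 highest-signal regions of the pooled list, without exception, so a list of the same length from the pooled regions is the same list.

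Coordinates are on dm6 (Release 6) and 1-based. The reference sequence was the Release 6 assembly, and all deposited dm6 regions lay within the lengths of its arms. Gene models were those of Ensembl release 115 (FlyBase annotation 6.54). The 13945 protein-coding genes on 2L, 2R, 3L, 3R, 4 and X were used, with every annotated transcript start as a transcription start. Other genes were left out. dm3 lists were used only for overlaps among themselves and for the ratio of peak numbers on X and the autosomes.

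The summit of a region is its deposited start plus its deposited summit offset. A region can hold several summits, each on its own line, and these were counted separately unless regions were merged. The top list of a replicate is its 7803 highest-signal regions, as many as there are optimal peaks. Regions were called overlapping when they shared at least 1 bp, and an optimal peak was called found in a replicate when its summit lay in a region of its top list. A summit within 1 kb of a transcription start was called a promoter peak of that gene, so a peak between 2 genes can count for both. Features were assigned in the order coding exon, 5' UTR, 3' UTR, other exon, intron, intergenic. Replicate values are the mean and SD over the 3 top lists. Chance overlap came from 100 random placements per replicate on the same arm, and chance promoter shares from 1000 random placements of the summits on the same arms, tested 1-sided.

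The comparisons, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, apart from the additions named as such. There were 21 gene lists, with 10 symbols matched through synonyms and none left unmatched. Of these, phm (taken as phtm), Tor (mTor), Dl (Delta) and rye (Taf12L) can also stand for other genes and were assigned by the list they belong to. Each was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists, and with 10000 random lists matched on 10 bins of gene length and on bins of the number of transcription starts (a permutation of genes within bins), two-sided, adjusted in the same way. The smallest p those lists can give is 0.0002 before adjustment. Motifs, 13 in all, were counted on either strand within 50 bp of the summit and in a window of the same width centred 300 bp to the left, and compared by an exact McNemar test, two-sided, with Benjamini-Hochberg adjustment. The trend of the E75/Hr3 site with signal was tested by permutation. The threshold was an adjusted p of 0.05. For a count of 0, the share that 3 genes would give is printed as the limit it allows, beside the upper end of the interval. Shares have exact Clopper-Pearson intervals and peak densities exact Poisson intervals, at 95%.

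By the rule for naming genes, Eip75B, EcR, usp, Eip74EF, br, Hr3, Hr4, ftz-f1 and Clk were always named, as were the genes with the start nearest to each of the 15 strongest optimal peaks, the 5 genes with the most summits in their body and all 20 members of the ecdysone hierarchy list. From every other list, up to 3 members with the highest-signal promoter peak and the first 2 members in alphabetical order without one were named. For heme synthesis and breakdown, only the number of bound members is given. CG1677, ush and the genes of the closing families were named after their values were seen.

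The calculations were tested on data with known answers. For 5000 of the optimal peaks, compared with shifted copies of part of them, the overlaps were the same as by direct comparison of all pairs, and all 200 genes given a simulated summit, among 13945, were found by the promoter step. Of lists drawn with raised odds of a promoter peak (4-fold), 66.5% were called among 13945 genes, and of lists with no change 0.313% were. The lists with raised odds had 19 to 24 members, so the share called among smaller lists was not tested. All 625 windows with a planted motif were found, and of 20 random sets of summits 0 were called in the promoter test. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

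Beside the settings above, the following were tried: reciprocal overlap of 50%, lists of 0.5 times the length, the whole lists, the dm3 lists, the 3901 optimal peaks with the highest signal, the pooled list, each replicate left out in turn, promoter distances of 500 bp and 2 kb, gene bodies in place of promoters, matched lists, the window on the right, 51 bp windows and 10 column-shuffled versions of each motif. Windows with the same GC content and the optimal peaks found in all 3 replicates were added after the data were seen. With 1 replicate left out, the optimal list was not remade. For promoters, the X ratio, genes and motifs, the top regions of the lower-numbered remaining replicate that overlapped a top region of the other were used. These numbered 6165, 6250 and 6122 without replicates 1, 2 and 3, fewer than the 7803 optimal peaks. Lost calls can therefore also come from the shorter lists. No lengths of the dm3 arms were used here, so for that build the numbers of peaks on X and on the autosomal arms were compared. For column-shuffled motifs no p was computed. There, a share was counted as passing when it lay above or below those of all 10 versions.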

Results

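Binding sites of Eip75B were mapped by ChIP-seq in whole prepupae of Drosophila melanogaster, the stage between the end of larval life and the pupa. Eip75B (E75) is a nuclear receptor whose gene is induced by the moulting hormone ecdysone, and its ligand pocket holds heme. The animals carried an eGFP exon inserted in an intron of Eip75B, so that chromatin bound by the tagged protein was precipitated with an antibody against GFP. Males and females were pooled. The labels give 1 group of 3 biological replicates and no second condition, so the comparisons are between replicates, between parts of the genome and between groups of genes. For each replicate, and for the replicates pooled, the deposited list held 30000 regions, background included, and a list of 7803 optimal peaks was deposited for the group. The number of reads is not given in the sources used here, so the depth is unknown. Intervals around shares cover counting error only.

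The gene of the tagged protein held more peak summits than any other protein-coding gene. Within the Eip75B gene (FBgn0000568; 3L, 17950953 to 18064696, minus strand, dm6), 38 optimal summits were found, and the top lists of the replicates held 37.0 ± 2.65 (SD, n = 3). The 33 other genes of similar length, from 102976 to 124993 bp, had a median of 4 summits and a highest number of 18, in CG1677. The density in Eip75B was 3.34 summits per 10 kb, against 0.583 per 10 kb over the 6 chromosome arms. Of the 38 summits, 35 lay in introns and 5 lay within 1 kb of 1 of the gene's 7 annotated transcription starts. A further summit within 1 kb of a start lay outside the gene.

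The strongest peak in the gene had its summit in an intron at 18011918, with an authors' signal value of 850, rank 186 in the optimal list. The next had its summit at 18009161, also in an intron, with a signal of 820. A peak with a signal of 668 had its summit in the 5' UTR at 17999791, 30 bp from a transcription start. Of the 38 summits, 22 lay in the top list of all 3 replicates, and 31 regions remained after overlapping regions were merged. The number was also 22 among the 3901 optimal peaks with the highest signal. After Eip75B, the genes with the most summits were kirre with 28, sbb with 25, Tet with 21 and Mnt with 20. In the replicates' top lists, kirre held 27.0 ± 4.58 (SD, n = 3) summits and sbb held 24.7 ± 0.577 (SD, n = 3). kirre is 394149 bp long and had 0.710 summits per 10 kb, whereas Mnt, of 29872 bp, had 6.70.

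**Figure D1:**
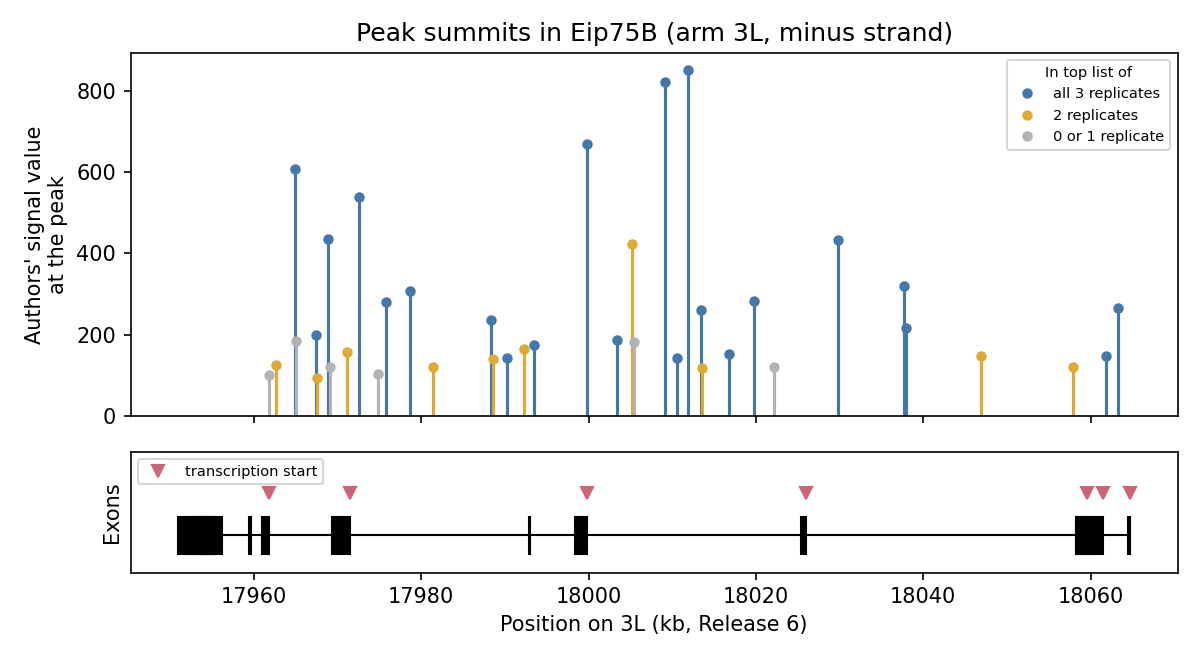
Peak summits in the Eip75B gene, with the position on arm 3L in kb (dm6) on the horizontal axis and the authors' signal value of each peak on the vertical axis, coloured by the number of replicates whose top list held the summit, above annotated exons (boxes) and transcription starts (triangles). The strongest peaks, with signals of 850 and 820, lie in an intron, and 22 of the 38 summits were in the top list of all 3 replicates.

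The strongest peaks were the same genomic sites in all replicates. The 15 optimal peaks with the highest signal all lay in the top list of every replicate, and none ranked below 20 in any of them. The peak ranked 1 had its summit at 481056 on 2L, within ush (476220 to 540560) and in an intron. Its nearest transcription start, 1368 bp away, was that of cbt, a zinc finger gene whose body does not hold the summit. The peak ranked 2, at 2703882 on X, lay 30 bp from the start of the UDP-galactose transporter gene Ugalt and had a signal of 3049. Of the 15 peaks, 9 lay within 1 kb of a start, those of Ugalt, CG14100, larp, PNPase, Lk6, CenG1A, CG18549, Chro and CG1888. The nearest starts to the others were those of cbt, CG11050, CG13323, osa, CG4004 and CG32772. The peak nearest to osa, which encodes a subunit of a chromatin remodelling complex, lay in an intron 13943 bp from the start, and the peak nearest to CG13323 was intergenic and 11924 bp away.

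To compare the replicates on lists of equal length, the 7803 highest-signal regions of each were taken as its top list. On average, 79.1% ± 0.281 (SD, n = 3) of a replicate's top regions overlapped a top region of another replicate. Randomly placed regions of the same widths on the same arms overlapped in 4.18% of cases on average and in 4.81% at most, over 100 placements per replicate. Of the optimal summits, 5091 (65.2%, 95% exact interval 64.2% to 66.3%) lay in a top region of all 3 replicates, 1879 in 2 of them, 782 in 1 and 51 in none. The share found in all 3 was 11.9% in the lowest quartile of signal, 60.0% in the next, then 93.1%, and 96.0% in the highest. Peaks of the lowest quartile lie nearest to the cut at 7803 regions, so small changes of rank take them out of a top list. Part of the rise therefore follows from the cut, and it does not show that weak peaks are absent from a replicate. Across peaks, the ranks of 2 replicates had a Spearman correlation of 0.704 to 0.774. Peaks are not independent replicates, and no p was computed because the optimal list was chosen on these replicates. With the whole lists of 30000 regions in place of the top lists, 95.7% of the optimal summits lay in a region of all 3 replicates.

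**Figure D2:**
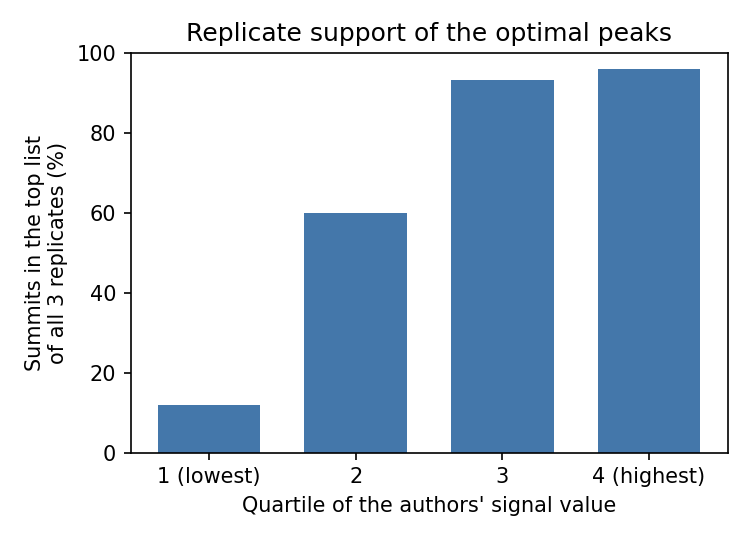
Share of optimal peak summits that lay in the top list of all 3 replicates, in percent on the vertical axis, by quartile of the authors' signal value on the horizontal axis. Bars rise from 11.9% in the lowest quartile to 96.0% in the highest. Part of the rise follows from the cut of the top lists, to which the lowest quartile lies nearest.

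Summits lay at promoters more often than randomly placed ones. Of the 7803 summits, 3311 (42.4%, 95% exact interval 41.3% to 43.5%) lay within 1 kb of the transcription start of a protein-coding gene, and the share in the replicates' top lists was 44.2% ± 1.84 (SD, n = 3). Random placements of as many summits on the same arms gave 20.3% on average and 21.8% at most. None of the 1000 placements reached the observed share (1-sided permutation p = 0.000999, the smallest that 1000 placements can give). By annotated feature, for which no random share was computed, 54.6% of summits lay in introns, 35.4% between genes, 8.38% in 5' UTRs, 1.09% in 3' UTRs and 0.538% in coding exons. The median distance to the nearest start was 1604 bp, and 1141 summits (14.6%) lay more than 10 kb from any start. The promoter share was 41.8%, 41.2%, 38.6% and 48.2% from the lowest to the highest quartile of signal.

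Peaks were about as dense on the X chromosome as on the large autosomal arms. Males in the pooled animals carry a single X, but the number of called peaks need not follow copy number. X had 59.6 optimal peaks per Mb, against 58.6 on 2L, 55.2 on 2R, 61.6 on 3L and 58.3 on 3R. The ratio of X to the mean of those 4 arms was 1.02, and in the replicates' top lists it was 1.00 ± 0.0592 (SD, n = 3). The ratio of X to the 4 arms pooled had a 95% interval, from counting error, of 0.962 to 1.08. The small chromosome 4, much of which is heterochromatic, had 24 optimal peaks, or 17.8 per Mb (95% exact Poisson interval 11.4 to 26.5), and 21.3 ± 6.11 (SD, n = 3) in the replicates' top lists. In the whole list of replicate 1, 287 regions lay on chromosome 4, against 126 and 146 in the lists of replicates 2 and 3.

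The genes of the ecdysone hierarchy had promoter peaks more often than other genes. Of the 20 listed genes, 17 (85%) had a summit within 1 kb of a start, the tagged gene Eip75B among them, against 23.5% of all other protein-coding genes (two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 21 lists, adjusted p = 8.16e-08). In the replicates' top lists, the share was 80.0% ± 8.66 (SD, n = 3). Random lists matched on bins of gene length and of the number of transcription starts had a mean of 51.7%. The list still passed against them (adjusted permutation p = 0.0252). Matching by bins does not make lengths equal within a bin. Only 307 genes are at least 50 kb long, Eip75B, EcR and br among them, whereas other members such as usp are short. Random genes drawn for the long members may be shorter, so an effect of gene length is not excluded. Both subunits of the ecdysone receptor were among the bound genes. EcR had 5 promoter peaks, the strongest with a signal of 166, and usp had 1, with its summit in the 5' UTR at 2041526 on X and a signal of 236.

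The early and mid-prepupal transcription factor genes were in the same group, in which not every member encodes a transcription factor. Eip74EF, an early gene encoding an Ets factor, had 3 promoter peaks, the strongest with a signal of 276, and 14 summits in its body. br, which encodes the Broad-Complex factors, had 2 promoter peaks, and the nuclear receptor gene Hr3 had 3. ftz-f1, which encodes the nuclear receptor that gives the mid-prepupal response its competence, had 2 promoter peaks, the stronger with a signal of 368 at 117 bp from a start, and 17 body summits. Hr4, Eip78C and Eip93F had 1 promoter peak each, Hr39, crc, tai and Eip63E had 2 each, and Blimp-1 had 3. Eip63F-1 and MsrA (listed as Eip71CD) had 1 each, that of MsrA found in the top list of 1 replicate. Hr4 and Eip78C had a promoter peak in the top lists of 2 replicates, and the other 14 bound members in those of all 3. The members with no promoter peak were Kr-h1, Cth (listed as Eip55E) and Smr, and Smr had 12 summits in its body.

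Cytosolic ribosomal protein genes were the other large group with frequent promoter peaks. Of 85 genes, 59 (69.4%) were bound, against 23.4% of other genes (Fisher's exact test, adjusted p = 8.96e-18), and the share in the replicates' top lists was 72.5% ± 6.04 (SD, n = 3). Matched random lists had a mean of 19.7% (adjusted permutation p = 0.0021). The strongest of these peaks were at RpS19b, with a signal of 775 at 893 bp from the start, RpL34b, with 673, and RpS27, with 664 at 13 bp from the start. The summit counted for RpS19b lay outside that gene, in an intron of another. RpL10 and RpL10Aa had none in the optimal list. For 51 of the 59 bound genes (86.4%), the strongest promoter peak was at least as near to their own start as to that of any other gene. Among all 3296 bound genes, this held for 2484 (75.4%). RpS19b, RpL34b and RpL10Aa have close paralogs, and how reads that fit both copies were placed is not given in the sources used here.

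Developmental signalling genes and genes of imaginal disc eversion also passed Fisher's exact test, but not the comparison with matched random lists. Of 25 signalling genes, 17 (68.0%) were bound (adjusted exact p = 1.66e-05). They included the EGF receptor ligand gene spi, with 6 promoter peaks and a highest signal of 663, brk, with a signal of 375, and Mad, with 252, whereas Ser and arm had none. Of 19 disc eversion genes, 11 (57.9%) were bound (adjusted exact p = 0.00486), with the highest signals at RhoGEF2 (335), Timp (312) and the myosin light chain gene sqh (284), and none at Idgf1 or Idgf3. Random lists matched on gene length and number of starts had means of 40.9% and 34.6%, with adjusted permutation p of 0.0504 and 0.144. Without replicate 3, both lists lost their call by Fisher's exact test (adjusted p = 0.0908 and 0.114), and without replicate 1 the disc eversion list did (adjusted p = 0.111). The peak lists used there held 6122 and 6165 peaks against 7803, so the losses cannot be credited to the replicate left out.

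Odorant and gustatory receptor, midgut digestion and testis-specific genes had promoter peaks less often than other genes by Fisher's exact test, and of these 3 lists the receptors alone also passed against matched lists. Of 119 odorant and gustatory receptor genes, 3 (2.52%) were bound, against 23.8% of other genes (Fisher's exact test, adjusted p = 1.50e-09; against matched lists, adjusted p = 0.0021). These were Or88a, with a signal of 363 at 847 bp from the start, Gr63a and Or9a, and Gr10a and Gr10b were among those without. Of 28 midgut digestion genes, Amy-d and Amy-p among them, 0 were bound, which allows a share of up to 10.7% (3 of 28 genes; upper end of the 95% exact interval 12.3%; Fisher's exact test, adjusted p = 0.00466; matched lists, adjusted p = 0.144). Of 27 testis-specific genes, Mst87F alone was bound, at 89 bp from its start, and Mst77F and Mst84Da were not (Fisher's exact test, adjusted p = 0.0332; matched lists, adjusted p = 0.272). The testis list did not pass without any 1 of the 3 replicates (adjusted exact p from 0.103 to 0.143). The peak lists used there held 6122 to 6250 peaks, fewer than the optimal list. Both tests treat genes as independent, but some members lie close together, such as Gr10a and Gr10b or Amy-d and Amy-p. The p for the receptor and midgut lists may therefore be too small.

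The other 14 lists did not pass Fisher's exact test after adjustment. Insulin and TOR signalling came nearest, with 10 of 22 genes bound (45.5%, adjusted exact p = 0.0598), among them melt, InR and Akt, and not Ilp1 or Ilp2. Of the other nuclear receptor genes, 6 of 13 were bound (adjusted exact p = 0.196), with the highest signals at Hr96 (549), Hnf4 (399) and ERR (386), and not at Hr38 or Hr51. With a summit anywhere in the gene or within 1 kb of it counted in place of a promoter peak, 9 of the 13 (69.2%) were bound and the list passed (adjusted exact p = 0.0136). Longer genes can hold more summits, and that setting was not compared with lists matched on length, so an effect of gene length is not excluded. For promoter peaks, matched random lists had a mean of 37.9% (adjusted permutation p = 0.760). The ERR peak lies between ERR and the autophagy gene Atg18a and was counted for both. In ecdysteroid synthesis, uptake and breakdown, 3 of 19 were bound, mld, woc and the ecdysone importer gene Oatp74D, and Cyp18a1 and Cyp6t3 were not (adjusted exact p = 0.690). None of the 11 late puff genes, such as Eig71Ea and Eig71Eb, and none of the 10 salivary glue genes, such as Sgs1 and Sgs3, was bound, which allows shares of up to 27.3% and 30.0% (3 genes of each list; upper ends of the 95% exact intervals 28.5% and 30.8%; adjusted exact p = 0.181 and 0.249).

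Among pathways of tissue breakdown, 6 of 16 cell death genes were bound (adjusted exact p = 0.411). The signals were 705 at the caspase inhibitor gene Diap1, 703 at the death activator gene hid and 140 at Decay, and Buffy and Damm had no promoter peak. In autophagy, 7 of 20 were bound (adjusted exact p = 0.466), with the highest signals at Atg2 (451), Atg17 (428) and Atg18a (386), and none at Atg1 or Atg10. Of 15 circadian clock genes, 5 were bound (adjusted exact p = 0.483), including sgg, cry and vri, whereas Clk, CkIIalpha and CkIIbeta were not. Clk had no summit in its body either. In heme synthesis and breakdown, 3 of 10 were bound (adjusted exact p = 0.784).

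In tissue-related groups, 5 of 14 larval fat body genes were bound, led by Apoltp, Sdr and NLaz, and not CCHa2 or Col4a1 (adjusted exact p = 0.483). In cuticle and chitin assembly 6 of 24 were bound, with Cht7, verm and knk the strongest and none at Acp1 or Ccp84Aa (adjusted exact p = 0.854). Of 26 immunity genes, 8 were bound (adjusted exact p = 0.483). The pathway genes imd, cact and dl had signals of 1039, 617 and 285, and the antibacterial peptide genes AttA and AttB had no promoter peak. Of 20 muscle genes, 3 were bound, Zasp52, sls and Tm1, and not Act57B or Act87E (adjusted exact p = 0.546), where matched lists had a mean of 41.1% (adjusted permutation p = 0.0731). Of 16 neuronal genes, 4 were bound (adjusted exact p = 1), among them elav with a signal of 881, Syx1A and Csp, and not Appl or ChAT.

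Over all 13945 protein-coding genes on the 6 arms, 3296 (23.6%) had a promoter peak. The replicates' top lists gave 3474 ± 116 genes (SD, n = 3), and 2442 genes had one in all 3 replicates and in the optimal list. The 3901 optimal peaks with the highest signal gave 1949 genes, and with them the signalling, disc eversion, midgut and testis lists no longer passed.

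**Figure D3:**
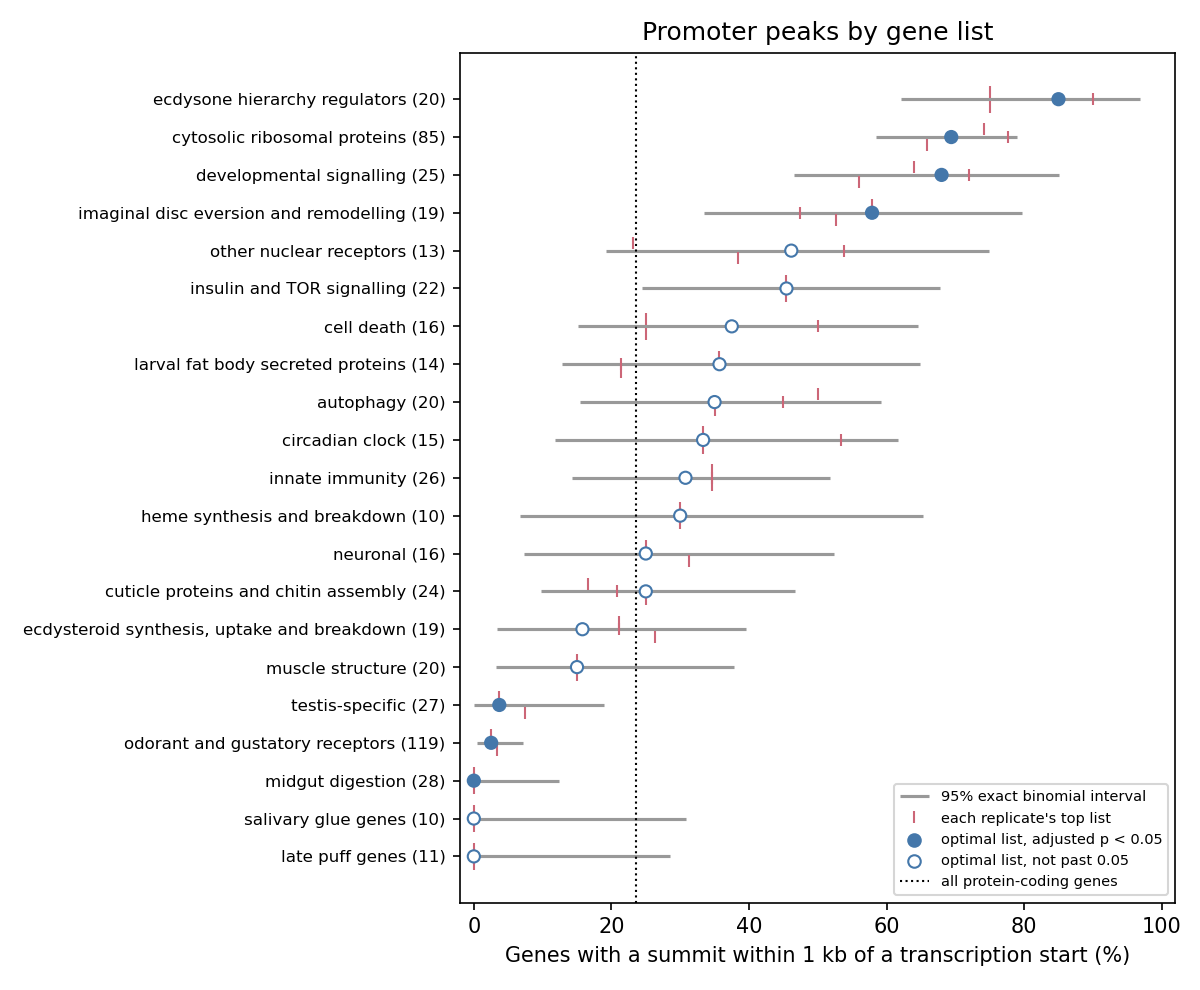
Share of genes with a summit within 1 kb of a transcription start, in percent on the horizontal axis, for each of the 21 gene lists, with the number of members in brackets: circles are the optimal list (filled where Fisher's exact test passed after adjustment), grey lines are 95% exact binomial intervals, red ticks are the 3 replicates' top lists and the dotted line is the share of all protein-coding genes, 23.6%. Ecdysone hierarchy regulators (85%) and cytosolic ribosomal proteins (69.4%) lie highest.

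To ask which sequences lie under the summits, 13 motifs were counted within 50 bp of each summit and in a window of the same width centred 300 bp to its left. The extended half-site bound by E75 and Hr3 was found at 0.730% of summits and in 0.487% of the flanking windows, a difference that did not pass (exact McNemar test, two-sided, Benjamini-Hochberg over the 13 motifs, adjusted p = 0.0998). In the replicates' top lists, the shares were 0.675% ± 0.112 at the summit and 0.410% ± 0.0128 in the flank (SD, n = 3). The core nuclear receptor half-site was at 2.51% of summits and in 1.97% of flanks (adjusted exact p = 0.0677). The Dref site, found at promoters of growth and replication genes, was higher at summits, at 0.871% against 0.256% (adjusted exact p = 2.52e-06), as was the GATA site, at 1.67% against 1.15% (adjusted exact p = 0.0264). The GAGA repeat was lower at summits, at 2.14% against 3.14% (adjusted exact p = 0.000649), and so was the E-box, at 0.743% against 1.23% (adjusted exact p = 0.0104).

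The other 7 motifs did not pass. The M1BP site was at 0.308% of summits against 0.141% of flanks and the Zelda site at 0.359% against 0.590% (both adjusted exact p = 0.0880), and the AP-1, Grainyhead, Ftz-f1, Ets and EcR/Usp sites had adjusted exact p from 0.160 to 1. The EcR/Usp inverted repeat was found at 2 summits and in 3 flanks. The E75/Hr3 site was at 0.564%, 0.769%, 1.03% and 0.564% of summits from the lowest to the highest quartile of signal, with no trend (two-sided permutation test with 100000 resamples, p = 0.771).

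The motif calls depended on the background. The mean GC content was 35.1% in the summit windows and 44.5% in the windows on the left. Against windows drawn from the same arm with the same GC content, a background chosen after the data were seen, the E75/Hr3 site passed (0.730% against 0.282%, adjusted exact p = 0.000445), the GAGA repeat turned to higher at summits (2.14% against 0.679%, adjusted exact p = 5.82e-14) and the GATA site and E-box did not pass (adjusted exact p = 0.561 and 0.850). The M1BP site (0.308% against 0.0256%, adjusted exact p = 6.82e-05) and the Grainyhead site (1.67% against 1.19%, adjusted exact p = 0.0385) also passed as higher, the Dref site stayed higher (0.871% against 0.410%, adjusted exact p = 0.00133), and the nuclear receptor half-site was at 2.43% of these windows (adjusted exact p = 0.942). Against the window on the right, the E75/Hr3 site also passed (0.730% against 0.320%, adjusted exact p = 0.00174). Mean GC content there was 44.5%, as on the left, where 38 windows held the site. The different calls on either side thus rest on few sites and not on mean GC content. The windows with the same GC content were drawn once, with a single random window per summit. The GATA site lost its call without each replicate in turn (adjusted exact p = 0.480, 0.108 and 0.0537 without replicates 1, 2 and 3), and the Zelda site passed as lower without replicate 1 (0.260% against 0.568%, adjusted exact p = 0.0357). The peak lists with 1 replicate left out held 6122 to 6250 peaks, fewer than the optimal list. Among the 3901 optimal peaks with the highest signal, the Dref site, the GATA site and the E-box lost theirs (adjusted exact p = 0.145, 0.177 and 0.0514), and in 51 bp windows the GAGA repeat and the GATA site did (adjusted exact p = 0.125 and 0.309).

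**Figure D4:**
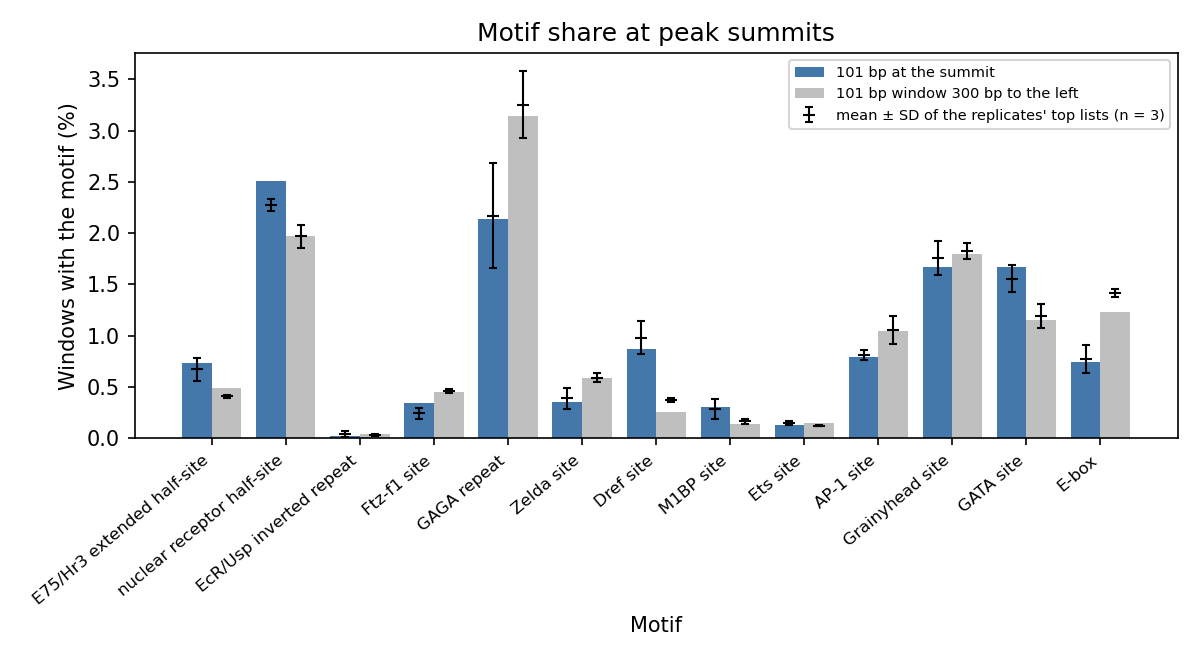
Share of windows with each of the 13 motifs, in percent on the vertical axis, within 50 bp of the summit (blue) and in the window 300 bp to the left (grey) for the optimal peaks, with the mean and SD of the 3 replicates' top lists in black. The Dref site (0.871% against 0.256%) and the GATA site (1.67% against 1.15%) are higher at the summit, and the GAGA repeat (2.14% against 3.14%) and the E-box (0.743% against 1.23%) lower.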

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

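Of the tests in this part, those of merged regions, of neighbouring genes and of AT-rich fragments were written down before their results were seen, and the others were chosen after. The design has 1 group, so no biological explanation was tested.

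On the older build, 4 optimal peaks lay outside the 6 chromosome arms, 3 on unplaced sequence (Uextra; highest signal 168) and 1 on X heterochromatin (XHet; signal 103). They stood out because sequences outside the arms enter none of the comparisons, and 4 is above the 3 that a count of 0 allows. The dm6 lists hold no region outside the arms. The cause was not tested.

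Eip75B held 38 summits, more than any of the 33 genes of similar length. Signal raised over the whole region would give its surroundings a like density, but the 100 kb to the left had 0.5 summits per 10 kb (95% exact Poisson interval 0.162 to 1.17) and the 100 kb to the right 1.70 (0.990 to 2.72), against 3.34 in the gene (2.36 to 4.59). The right side was thus also dense for the genome, and its interval overlaps that of the gene. Counting overlapping regions more than once is argued against by the 31 regions left after merging, against at most 17 in genes of similar length merged in the same way. An effect of the tag at its own locus stays open and cannot be told apart from binding, because no sample lacks the tag: by density, Eip75B ranked 2 of 307 genes of at least 50 kb, after the untagged ftz-f1 (3.35 per 10 kb), which does not show what the tag does at Eip75B.

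Ribosomal protein genes had promoter peaks at 59 of 85 members. Of the 59, 51 (86.4%) had their strongest promoter peak nearest to their own start, ties included, as did 75.4% of all bound genes. Peaks that belong to neighbouring genes are argued against, since on such peaks alone 60.0% of members were bound against 17.6% of other genes (Fisher's exact test, two-sided, adjusted p = 8.55e-17). Peaks at all constitutively expressed genes are argued against by proteasome, respiratory chain and vacuolar ATPase subunits, chosen after the data were seen. Of these, 33 of 161 (20.5%, 95% exact interval 14.5% to 27.6%) were bound, below the 58.5% to 79.0% of the ribosomal protein genes. Shares were higher for mitochondrial ribosomal proteins (38.4%, upper end of the interval 50.5%), Rab GTPases (35.5%, 54.6%) and translation initiation factors (31.8%, 47.6%). Those upper ends also lie below 58.5%. RNA polymerase subunits had 25.8% and small nuclear ribonucleoproteins 12.5%. Which families are constitutively expressed was not tested. Signal that follows very high transcription, with no binding of Eip75B, stays open, because expression was not analysed here, and so does binding by Eip75B.

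Summit windows were AT-rich, with a mean GC content of 35.1% against 44.5% on the left, and motif shares moved with the background. Base composition may account for the lower E-box share, which in windows of the same GC content differed by -0.0897 percentage points (exact McNemar test, two-sided, adjusted p = 0.850), and the GAGA repeat was then higher at summits. For the E75/Hr3 site, GC content alone is argued against, since the share was higher than in these windows by 0.449 percentage points (the same exact test, adjusted p = 0.000445). The windows, from a single random draw, match arm and GC content but not base order or distance to genes, so composition in a wider sense stays open. Against the planned window on the left, the site had not passed (the same exact test, adjusted p = 0.0998). A preference for AT-rich fragments in the library stays open. The equal windows of the genome with a GC content of up to 32.2% held 0.678 times the average number of summits (95% exact Poisson interval 0.621 to 0.738), the value set beforehand to count against it, although these may hold sequence that reads map to poorly. From 32.2% to 39.9% the number also rose with GC content, from 1.14 to 1.43 times the average, which goes against such a preference, but above 44.1% it fell from 1.05 to 0.247 times, which goes with it.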

How the results depend on the processing

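Windows of the same GC content and the restriction to peaks found in all 3 replicates were chosen after the data were seen, and the other alternatives were planned. Taking the highest-signal pooled regions changed nothing, since they are the same list by construction. Under every alternative run, the promoter share stayed above random placement, the X to autosome ratio moved by less than the SD of the replicates and the E75/Hr3 site had no trend.

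The replicate overlap, 79.1%, was 70.3% with reciprocal overlap of 50%, 79.9% with lists of 0.5 times the length, 74.8% with every region, and 78.3% to 80.0% with 1 replicate left out. The share of optimal peaks found in all replicates was 46.6%, 67.1%, 95.7% and 72.3% to 74.5% in the same order, where fewer replicates and longer lists make it easier to meet. Among the 3901 peaks with the highest signal, fewer by construction, 1949 genes had a promoter peak, Eip75B held 22 summits, 3 gene lists passed in place of 7, and 1 motif in place of 4. With only peaks found in all replicates, Eip75B held 22 summits and 3 lists passed. Matched random lists left 3 lists, and 51 bp windows 2 motifs. With 1 replicate left out, and so with 6122 to 6250 peaks, 4 to 6 lists passed, and without replicate 3 the number was 4. The E75/Hr3 site passed against the window on the right (difference 0.410 percentage points) and windows of the same GC content (0.449), and lay above all 10 column-shuffled motifs (0.472 above their mean). Except for list length and number of replicates, the cause was not tested.

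Among single lists, 20 values turned direction, 20 lost and 1 gained their call, and 169 kept both. Among single motifs, the E75/Hr3 site included, 17 turned, 11 lost and 6 gained their call, and 96 kept both. The numbers that kept both include the highest-signal pooled regions, the same list by construction, where all 21 lists and all 13 motifs could not change. The gains with the direction kept were those of the other nuclear receptors over gene bodies, the E75/Hr3 site (3), the M1BP site with windows of the same GC content and column-shuffled motifs, and the Zelda site without replicate 1. The GAGA repeat and the Grainyhead site turned and passed as higher with windows of the same GC content. Of the lists that turned, none passed in either setting. Among the 3901 peaks with the highest signal, the shares were 12.5% for cell death, 10% for heme, 8.33% for cuticle, 15% for muscle and 12.5% for neuronal genes. With 1 replicate left out they were 12.5% to 16.7% for cuticle genes, 15.8% to 21.1% for ecdysteroid synthesis (turned without replicate 2), 18.8% for cell death without replicates 2 and 3, and 20% to 30% for heme (turned without replicate 3). Peaks in all replicates gave 7.14% for fat body and 8.33% for cuticle genes. Heme genes had 20% at 500 bp, cuticle and neuronal genes 25% at 2 kb, and cuticle genes 25% over gene bodies. Against matched lists, clock genes differed by -10.1 and neuronal genes by -24.6 percentage points.

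Among motifs, the Ets site turned to higher at summits by 0.0513 percentage points among the 3901 with the highest signal, 0.0162 to 0.0800 with 1 replicate left out, 0.0589 with peaks in all replicates and 0.0256 in 51 bp windows. Windows of the same GC content turned the Ftz-f1 site (0.103), the GAGA repeat (1.46), the Zelda site (0.0769) and the Grainyhead site (0.474). Column-shuffled motifs turned the nuclear receptor half-site (-0.505), the EcR/Usp repeat (0.0103), the Ftz-f1 site (0.142), the GAGA repeat (1.46), the Ets site (0.0128), the Grainyhead site (0.254) and the GATA site (-0.705). The cause was not tested.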

Other observations

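All tests in this part were chosen after the data were seen, and they are reported as values without explanation.

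Mitochondrial ribosomal protein genes also had frequent promoter peaks. Of 73, 28 (38.4%) were bound, against 23.6% of other genes (Fisher's exact test, two-sided, Benjamini-Hochberg over 22 added gene families, adjusted p = 0.0230), and the share in the replicates' top lists was 39.7% ± 5.48 (SD, n = 3). Matched random lists had a mean of 13.4% (adjusted permutation p = 0.0022). The strongest of these peaks were at mRpS23, with a signal of 2219, mRpS10, with 1848, and mRpL41, with 1817. The peak at mRpS23 is the 1 named above for CenG1A, whose start is nearer.

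The E(spl) complex, whose genes respond to Notch, had 5 of 11 genes bound, among them E(spl)m3-HLH with a signal of 532. It passed against matched lists (mean 11.7%, adjusted p = 0.0308) and not by Fisher's exact test (adjusted p = 0.320). Of the 8 Hox genes, 0 had a promoter peak, which allows a share of up to 37.5% (3 genes; upper end of the 95% exact interval 36.9%), and the share in the replicates' top lists was 4.17% ± 7.22 (SD, n = 3). For Hox genes, matched lists had a mean of 47.5% (adjusted p = 0.0308; by Fisher's exact test, adjusted p = 0.361). Both tests treat genes as independent, whereas members of a gene complex lie close together and can share a peak. The p for these 2 families may therefore be too small. Antp had 8 summits in its body, Ubx 3, Abd-B 2 and lab 1.

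Of 85 cytochrome P450 genes, 6 were bound (7.06%; Fisher's exact test, adjusted p = 0.000684; matched lists, adjusted p = 0.00293), with the strongest peak at Cyp6u1 (657). Of the odorant-binding, CheB and ionotropic receptor genes, 6 were bound (4.88%; the same exact and matched tests, adjusted p = 2.73e-07 and 0.0022). Of 118 histone genes, 4 were bound (3.39%; the same exact and matched tests, adjusted p = 5.14e-08 and 0.0231), with His2Av the strongest at 333, and most histone genes lie in a repeated cluster where reads fit many copies. Cpr cuticle genes (5 of 70) and pickpocket channel genes (1 of 29) were lower by Fisher's exact test (adjusted p = 0.00311 and 0.0265) and not against matched lists (adjusted p = 0.123 and 0.0547). For these families too, both tests treat genes as independent. Where members lie close together, as most histone genes do, the p may be too small. Over the 22 families, 1 was higher and 5 were lower by Fisher's exact test, and 2 were higher and 4 lower against matched lists.

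Stronger peaks had more AT-rich centres. The mean GC content within 50 bp of the summit was 37.6%, 36.1%, 34.6% and 32.0% from the lowest to the highest quartile of signal, while that of the windows on the left was 43.3%, 44.5%, 44.9% and 45.4%. In the replicates' top lists, the centre had 35.5% ± 0.987 (SD, n = 3), and the 6 arms had 42.2%. Across the same quartiles, the share of the GAGA repeat went from 3.54% to 0.820% (two-sided permutation test, Benjamini-Hochberg over the 13 motifs, adjusted p = 0.00013), that of the M1BP site from 0.564% to 0.103% (adjusted p = 0.025) and that of the Dref site from 1.23% to 0.410% (adjusted p = 0.0442). The Dref site was at 1.84% of promoter summits, against 0.513% of their flanks (exact McNemar test, adjusted p = 5.01e-06), and no other motif passed at promoter summits. At the other summits, the nuclear receptor half-site (2.85% against 1.94%, exact McNemar test, adjusted p = 0.0240) and the GATA site (1.91% against 1.22%, adjusted p = 0.0302) were higher than in the flanks. The GAGA repeat (1.47% against 2.89%, adjusted p = 4.59e-05), the E-box (0.512% against 1.16%, adjusted p = 0.00594) and the AP-1 site (0.690% against 1.22%, adjusted p = 0.0302) were lower in the same exact test. The GC content of these summit windows was 33.5%, against 45.4% on the left, and over all summits the half-site and the GATA site did not pass against windows of the same GC content (exact McNemar test, adjusted p = 0.942 and 0.561).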
